A study of Bos taurus with 20 samples.

How the data were processed

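RNA was measured in 20 whole bovine conceptuses, 1 library per conceptus, from total RNA depleted of ribosomal RNA and sequenced as paired reads of 150 nucleotides, per the labels' protocols. The deposited values are raw fragment counts per Ensembl gene, made with featureCounts 2.0.1 without strand, over exons summed by gene, on a BAM from which duplicates had been removed, per the file headers. Reads marked as duplicates were ignored and the command has no option for reads with several alignments, per the file headers. The annotation was Ensembl release 105 of the assembly ARS-UCD1.2, per the file headers. HISAT2, SAMtools and Picard are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. Without strand, reads of a gene and of an antisense partner cannot be told apart, and reads shared between near-identical copies are not counted, so genes of multigene families are uncertain.

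All 27607 genes of the files were read, of which 2831 had 0 counts in all 20 libraries. The files pair gene identifiers with positions but not with names. The gene table at hand is of the assembly ARS-UCD2.0, and 0 of the 27607 identifiers matched it. No symbol is therefore printed, and positions are those of the files on ARS-UCD1.2. The 17 biological gene lists and 4 marker lists fixed before the data were examined could not be tested, because 0 members could be matched. Tests over the genes of each chromosome took their place and were chosen after it was seen that the files name no genes.

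Groups, sex and treatment came from the labels. Titles open with a code whose meaning the labels do not give, here called the title code. Codes c201, c5036 and c8086 hold controls and codes c6186 and c9007 hold IL6 conceptuses, so treatment and title code are nested. Each library is a separate conceptus. Where conceptuses of one title code are alike for a reason of their own, p-values of the IL6 comparisons are too small.

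Genes were kept with the default expression filter of edgeR 4.0.16 by group, which left 14875 genes. One quasi-likelihood model in edgeR with robust dispersions, TMM factors, 4 group terms and a term for sex was fitted to all 20 libraries, so that groups share one estimate of the spread. Each comparison is a contrast of that model, with the Benjamini-Hochberg adjusted p under 0.05 as the threshold and no minimum fold. If no gene differed, 743.75 of the 14875 genes would on average have an unadjusted p under 0.05. The difference of the IL6 effect between the sexes was fitted to the 12 ovoid conceptuses alone, over 13274 genes. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values were computed here from the counts with TMM factors. Chromosome groups with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and, in addition, an estimated correlation, adjusted over 31 groups per comparison. Shares of counts and library totals were compared with two-sided exact permutation tests, or with 100000 permutations where both groups held 10 conceptuses, and adjusted over 9 tests. R 4.3.3, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were the other tools.

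The rule for named genes, fixed before the data were examined, needed symbols. Without them at most 2 identifiers with a positive and 2 with a negative fold change are printed per comparison. These are the largest changes past the threshold with a mean log2 CPM of at least 1, or, where none passed on that side, those with the smallest p, given as values. Parts of the rule that list genes by symbol were not used here.

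The tests were checked on simulated counts for the real genes, drawn from the means, dispersions and library sizes of the 20 libraries with 200 genes changed. The simulated counts hold no title code effect and no library with a profile of its own. Their recovery and false calls therefore need not hold for the real IL6 comparisons. Between ovoid IL6 and ovoid control conceptuses, edgeR recovered 20 of 100 genes changed 2-fold and 71 of 100 changed 4-fold among 14817 genes, with 3 false calls. DESeq2 recovered 45 and 84 in those same simulated counts, with 36 false calls. For the tubular IL6 comparison edgeR recovered 12 of 100 genes at 2-fold and 56 of 100 at 4-fold among 14834 genes. For males against females it recovered 37 and 84 of 100 among 14816 genes.

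Alternatives were RLE factors, DESeq2, no low-count filter, a CPM above 1 in at least 4 libraries, a minimum absolute log2 fold change of 1, removal of the 37 mitochondrial genes, each conceptus left out, each title code left out, the title code as a random block or fixed term, sample quality weights, no sex term, fits on fewer groups, and counts summed per title code and shape. Ribosomal RNA genes are not named in the files, so only mitochondrial genes were removed in the sixth of these. Fits without the shallowest library joined with another choice, and DESeq2 fits without a title code, were chosen after the data were seen. Total counts ran from 329666 to 13940103 per library. Floors of 3 counts cover counting error only. In 42 pairs of libraries of one group, chi-square per degree of freedom over genes was 13.8 or more, so no pair looked like copies of 1 library, which is all that this comparison with counting noise can show.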

Results

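Bovine conceptuses that had been exposed as embryos to recombinant bovine interleukin 6 (IL6, a cytokine) or to its carrier were compared by RNA sequencing. IL6 was added at 100 ng/ml on day 5 after fertilisation in vitro, and embryos stayed in the treated drops until day 7.5, when blastocysts were collected for transfer. The title of the series states an interest in elongation of the conceptus and in its transcriptome. The conceptuses were ovoid or tubular in shape, with 6 ovoid control, 6 ovoid IL6, 4 tubular control and 4 tubular IL6 conceptuses. Sex was given for each, with 10 males and 10 females. Ovoid controls held 3 females and 3 males, ovoid IL6 4 females and 2 males, tubular controls 1 female and 3 males, and tubular IL6 2 females and 2 males.

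Counts assigned to genes ranged from 329666 to 13940103 in ovoid controls, 2298491 to 10296130 in ovoid IL6, 6997220 to 12138818 in tubular controls and 4845404 to 11366747 in tubular IL6 conceptuses. The lowest total belonged to ovoid control replicate 3, in which 15567 genes had a count, against 18339 to 19937 in the other ovoid controls. Its median Spearman correlation across genes with the other libraries was 0.62, against 0.950 to 0.966 for the other ovoid controls. The 6 conceptuses of title code c6186, all given IL6, had 2298491 to 6262473 counts, and the 4 of title code c9007, also given IL6, had 8589036 to 11366747. The mean log2 total did not differ detectably between IL6 and control ovoid conceptuses (difference 0.10, exact permutation p = 0.948, adjusted p = 0.948; without ovoid control replicate 3 it was -0.69, with the IL6 libraries shallower, exact permutation p = 0.117) or between IL6 and control tubular conceptuses (difference -0.33, exact permutation p = 0.371, adjusted p = 0.600). The share of counts in the 10 most abundant genes was 8.35% ± 1.64 (SD, n = 6) in ovoid IL6 and 7.64% ± 1.42 (SD, n = 6) in ovoid control conceptuses (exact permutation p = 0.405, adjusted p = 0.600). In tubular conceptuses it was 8.94% ± 3.49 (SD, n = 4) with IL6 and 7.45% ± 0.103 (SD, n = 4) in controls (exact permutation p = 0.714, adjusted p = 0.804).

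**Figure D1:**
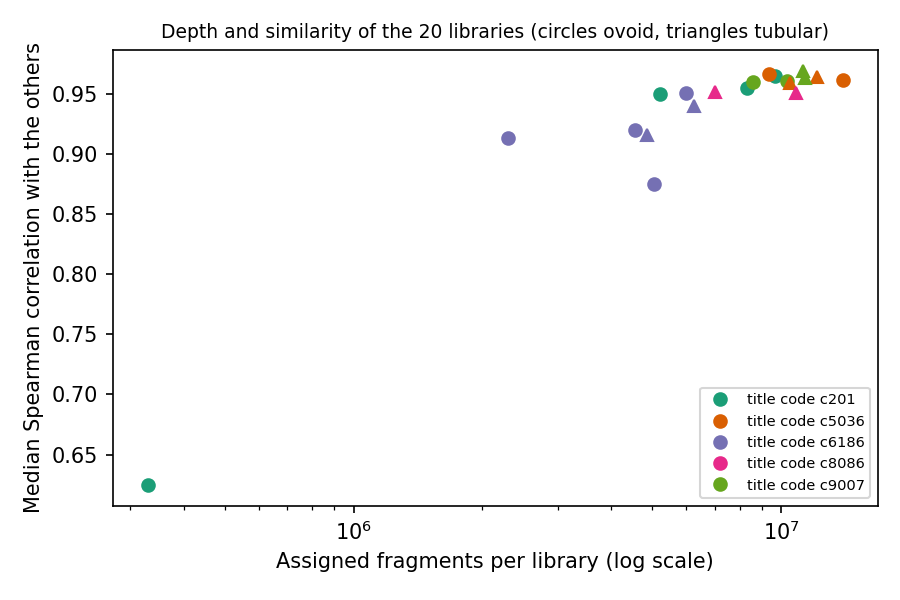
Fragments assigned to genes per library on a log scale (x axis) against the median Spearman correlation of the library with the other 19 (y axis), coloured by title code, with circles for ovoid and triangles for tubular conceptuses. Ovoid control replicate 3 lies apart at 329666 fragments and a correlation of 0.62.

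In ovoid conceptuses, no gene passed the threshold between IL6 and control. ENSBTAG00000054829 (chromosome 1, 626079 to 668340) measured 13.5 ± 13.1 CPM (SD, n = 6) with IL6 and 0.481 ± 0.397 CPM (SD, n = 6) in controls, a log2 fold change of 4.54 ± 0.89 (SE, edgeR adjusted p = 0.304), and ENSBTAG00000043985 (chromosome 12, 46109476 to 46548484) had a log2 fold change of 4.36 ± 0.86 (SE, edgeR adjusted p = 0.304). In ovoid conceptuses both rest on title code c6186. The first was at 0.577 and 1.48 CPM in the 2 ovoid conceptuses of c9007, and without c6186 DESeq2 gave log2 fold changes of 0.87 ± 1.03 and 0.32 ± 0.96 (SE). Both genes had at most 7 counts in any ovoid control library, so the sizes of their fold changes are uncertain. Toward lower values, ENSBTAG00000022813 (chromosome 18, 62159120 to 62167311) measured 5.75 ± 3.97 CPM (SD, n = 6) with IL6 and 39.9 ± 24.1 CPM (SD, n = 6) in controls, a log2 fold change of -2.74 ± 0.51 (SE, edgeR adjusted p = 0.304). The highest IL6 value of that gene, 12.97 CPM, lay below the lowest control value, 14.9 CPM. ENSBTAG00000007383 (chromosome 24, 31380664 to 31692928) had a log2 fold change of -2.03 ± 0.48 (SE, edgeR adjusted p = 0.334). The first of these genes overlaps 1 other annotated gene and the last overlaps 2. Mitochondrial genes took 2.50% ± 0.744 (SD, n = 6) of the counts with IL6 and 1.52% ± 0.706 (SD, n = 6) in controls, a difference that passed before adjustment but not after it (exact permutation p = 0.0433, adjusted p = 0.195). Without ovoid control replicate 3 the control mean was 1.73% (exact permutation p = 0.0996). By title code, the IL6 mean was 2.72% in the 4 conceptuses of c6186 and 2.05% in the 2 of c9007, while the 4 ovoid controls of c201 averaged 1.26% and the 2 of c5036 had 2.69% and 1.41%, so the difference rests on the control code c201 as well. As a group, 24 of the 27 tested mitochondrial genes had a positive and 3 a negative fold change (camera adjusted p = 1.84e-04), which was not kept with an estimated correlation (adjusted p = 0.998) or without ovoid control replicate 3 (camera adjusted p = 0.0975).

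Of 14875 genes, edgeR called 0 in ovoid conceptuses, with 1241 at an unadjusted p under 0.05, of which 793 were higher and 448 lower with IL6, while of all genes 7691 had a positive and 7184 a negative fold change. Of 100 splits of the ovoid conceptuses, the real one included, 34 gave 1241 or more. Fits without 1 conceptus gave edgeR counts at an unadjusted p under 0.05 from 826 (without ovoid IL6 replicate 3) to 1522 (without ovoid control replicate 4). DESeq2 called 86, of which 70 were higher and 16 lower, with 1489 at an unadjusted p under 0.05. Without c6186 it called 10 higher and 15 lower, and without c9007 511 higher and 230 lower. ENSBTAG00000022813 and ENSBTAG00000007383 were the 2 of these 86 that DESeq2 also called without title code c6186 (adjusted p = 0.0118 and 0.0445), and it called both without c9007 (adjusted p = 9.26e-04 and 2.19e-03). Both fits used the same controls. Over both shapes ENSBTAG00000007383 averaged 3.97 CPM in c6186 and 4.27 CPM in c9007. Control code c201 was close to these at 4.65 CPM (0 to 8.46), while c5036 averaged 10.7 and c8086 10.9 CPM. Treatment is nested in title code, and the edgeR count moved with it. Without c9007 edgeR called 154 genes and without c6186 it called 0, and without ovoid IL6 replicate 5 alone it called 11. Leaving out c9007 kept 4 ovoid IL6 conceptuses and leaving out c6186 kept 2, so these counts also differ in sample size.

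In tubular conceptuses, no gene passed the threshold between IL6 and control either. ENSBTAG00000009055 (chromosome 23, 39178911 to 39266796) measured 27.7 ± 8.72 CPM (SD, n = 4) with IL6 and 12.3 ± 2.02 CPM (SD, n = 4) in controls, a log2 fold change of 1.22 ± 0.31 (SE, edgeR adjusted p = 0.9997). ENSBTAG00000020654 (chromosome 2, 36715262 to 37045806) had a log2 fold change of 1.30 ± 0.37 (SE, edgeR adjusted p = 0.9997). On the lower side, ENSBTAG00000013557 (chromosome 7, 96168529 to 96204132) measured 8.17 ± 5.63 CPM (SD, n = 4) with IL6 and 20.3 ± 5.78 CPM (SD, n = 4) in controls, a log2 fold change of -1.85 ± 0.54 (SE, edgeR adjusted p = 0.9997), and ENSBTAG00000014920 (chromosome 4, 36966817 to 37237011) had one of -3.93 ± 1.18 (SE, edgeR adjusted p = 0.9997). The latter measured 0.147 ± 0.174 CPM (SD, n = 4) with IL6, at most 4 counts per library, and 5.07 ± 5.55 CPM (SD, n = 4) in controls. Its fold change therefore rests on values near 0 and is uncertain in size. The mitochondrial share was 2.85% ± 0.695 (SD, n = 4) with IL6 and 2.25% ± 0.473 (SD, n = 4) in controls (exact permutation p = 0.229, adjusted p = 0.514). Of the 514 tested genes of chromosome X, 175 had a positive and 339 a negative fold change with IL6, with a median log2 fold change of -0.16 (camera adjusted p = 5.43e-03). With an estimated correlation that test gave an adjusted p = 0.960. Chromosome 13 gave a median of -0.14 over 550 genes (camera adjusted p = 0.0211), with an adjusted p = 0.960 with an estimated correlation. Of 14875 genes, edgeR called 0, with 374 at an unadjusted p under 0.05, and DESeq2 called 0, with 629. Both counts lie below the 743.75 expected with no difference, so they are no sign of an effect. Leaving out 1 conceptus moved the 374 of edgeR to values from 109 (without tubular IL6 replicate 1) to 748 (without ovoid control replicate 3). Without c9007 edgeR called 0 and DESeq2 302, and without c6186 they called 0 and 3. Both of these fits kept the same number of tubular IL6 conceptuses, but the one without c6186 kept fewer conceptuses over both shapes.

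**Figure D2:**
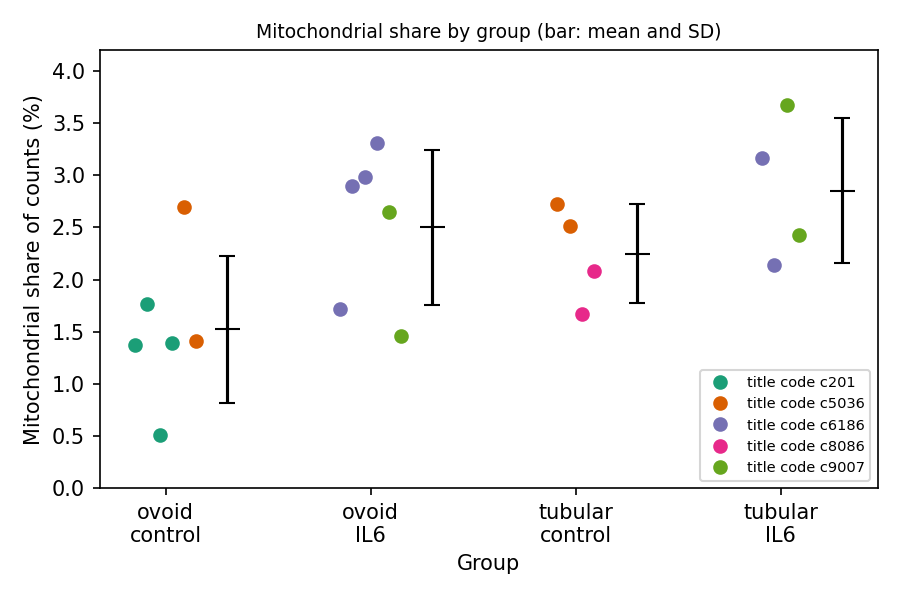
Share of counts in mitochondrial genes (y axis, percent) in each of the 20 conceptuses by group (x axis), coloured by title code, with the mean and SD beside the points. Ovoid IL6 conceptuses averaged 2.50% and ovoid controls 1.52%.

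Averaged over both shapes, the IL6 comparison again had no gene past the threshold. ENSBTAG00000054829 had a log2 fold change of 3.96 ± 0.69 (SE, edgeR adjusted p = 0.205) and measured 5.85 ± 2.99 CPM (SD, n = 4) in tubular IL6 against 0.494 ± 0.534 CPM (SD, n = 4) in tubular control conceptuses. Over both shapes it measured 15.6 ± 10.97 CPM (SD, n = 6) in c6186 and 2.62 ± 2.06 CPM (SD, n = 4) in c9007, and DESeq2 without c6186 gave 1.96 ± 0.74 (SE, DESeq2 adjusted p = 0.349). ENSBTAG00000025450 (chromosome 10, 76116422 to 76386867) measured 218 ± 125 CPM (SD, n = 6) in ovoid IL6 and 60.7 ± 14.7 CPM (SD, n = 6) in ovoid control conceptuses, with an averaged log2 fold change of 1.55 ± 0.30 (SE, edgeR adjusted p = 0.205). It measured 270 ± 68.5 CPM (SD, n = 6) in c6186 but 89.0 ± 20.5 CPM (SD, n = 4) in c9007, against means of 56.5 to 78.2 CPM in the control codes, and DESeq2 without c6186 gave 0.29 ± 0.18 (SE, DESeq2 adjusted p = 0.635). ENSBTAG00000022813 had an averaged log2 fold change of -2.16 ± 0.40 (SE, edgeR adjusted p = 0.205), with 8.26 ± 7.35 CPM (SD, n = 6) in c6186 and 13.1 ± 8.73 CPM (SD, n = 4) in c9007, against 39.8 ± 28.4 (SD, n = 4) in c201, 47.2 ± 15.1 (SD, n = 4) in c5036 and 46.7 ± 30.3 (SD, n = 2) in c8086. On the same side was ENSBTAG00000005082 (chromosome 5, 82772595 to 82782365), with an averaged log2 fold change of -0.57 ± 0.13 (SE, edgeR adjusted p = 0.205), and without c6186 DESeq2 gave -0.37 ± 0.16 (SE, DESeq2 adjusted p = 0.436). Over both shapes, 23 of 27 mitochondrial genes had a positive fold change (camera adjusted p = 1.54e-03), with an adjusted p = 0.920 with an estimated correlation and 0.140 without ovoid control replicate 3. With edgeR, 0 genes were called and 1591 had an unadjusted p under 0.05, 1171 of them higher and 420 lower with IL6, while of all 14875 genes 7369 had a positive and 7506 a negative fold change. That edgeR count of 1591 ran, with 1 conceptus left out, from 928 (without tubular IL6 replicate 1) to 2471 (without ovoid control replicate 3). DESeq2 called 143, of which 116 were higher and 27 lower, with 2065 at an unadjusted p under 0.05. That balance was not kept by DESeq2 without c6186 (12 higher, 26 lower) or without c9007 (1029 higher, 1034 lower). Without c9007 edgeR called 344 genes, and without c6186 0. Those fits kept 6 and 4 IL6 conceptuses.

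The difference of the IL6 effect between tubular and ovoid conceptuses had no gene past the threshold. ENSBTAG00000008714 (chromosome 1, 128385395 to 128561717) had the smallest p among positive values, with a log2 difference of 3.14 ± 0.93 (SE, edgeR adjusted p = 1), which became 2.02 without tubular IL6 replicate 2. ENSBTAG00000032446 (chromosome 3, 18249209 to 18251674) had the smallest among negative values, -1.29 ± 0.49 (SE, edgeR adjusted p = 1). Of the 514 genes of chromosome X, 165 had a positive and 349 a negative difference (camera adjusted p = 0.0158), with an adjusted p = 0.980 with an estimated correlation. With edgeR, 0 of 14875 genes were called and 94 had an unadjusted p under 0.05, and DESeq2 called 0, with 142. Both counts lie far below the 743.75 expected with no difference. In simulated counts edgeR recovered 2 of 100 genes changed 2-fold for this difference, so the absence of calls is weak evidence of none. In fits that left out 1 conceptus the 94 of edgeR became values from 73 (without ovoid IL6 replicate 3 or 4) to 177 (without ovoid IL6 replicate 2).

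Tubular and ovoid shapes were compared within each treatment. Among controls, no gene passed the threshold. ENSBTAG00000013901 (chromosome 14, 67893306 to 67960782) measured 204 ± 27.6 CPM (SD, n = 4) in tubular and 119 ± 28.8 CPM (SD, n = 6) in ovoid controls, a log2 fold change of 0.71 ± 0.26 (SE, edgeR adjusted p = 0.9998), and ENSBTAG00000009895 (chromosome 18, 45515132 to 45556175) had one of 0.71 ± 0.26 (SE, edgeR adjusted p = 0.9998). ENSBTAG00000037795 (chromosome 26, 16125969 to 16208881) had a log2 fold change of -3.39 ± 0.92 (SE, edgeR adjusted p = 0.9998), and ENSBTAG00000007666 (chromosome 1, 81402025 to 81572413) one of -1.13 ± 0.32 (SE, edgeR adjusted p = 0.9998). ENSBTAG00000037795 measured 0.487 ± 0.249 CPM (SD, n = 4) in tubular controls, at most 9 counts per library. In ovoid controls it measured 4.64 ± 5.90 CPM (SD, n = 6), so the size of its fold change is uncertain. Of the 27 mitochondrial genes, 24 had a positive fold change in tubular controls (camera adjusted p = 3.77e-08, and adjusted p = 0.971 with an estimated correlation), and the mitochondrial share was 2.25% in tubular and 1.52% in ovoid controls (exact permutation p = 0.114, adjusted p = 0.343). Without ovoid control replicate 3 that difference was 0.52 percentage points (exact permutation p = 0.183) and without ovoid control replicate 5 it was 0.96 (exact permutation p = 0.0238). By title code the mean share was 1.26% in c201, which holds ovoid controls alone, 2.34% in c5036 and 1.87% in c8086. On chromosome 13, 365 of 550 genes had a positive fold change (camera adjusted p = 0.0215, and adjusted p = 0.971 with an estimated correlation). With edgeR, 0 of 14875 genes were called and 244 had an unadjusted p under 0.05, and DESeq2 called 0, with 402. Both counts lie below the 743.75 expected with no difference. The edgeR count of 244, with 1 conceptus left out, ran from 155 (without ovoid control replicate 3) to 560 (without ovoid control replicate 5).

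Among IL6 conceptuses, no gene passed the threshold between shapes. ENSBTAG00000013888 (chromosome 21, 47777670 to 47782907) measured 19.1 ± 4.36 CPM (SD, n = 4) in tubular and 7.45 ± 3.20 CPM (SD, n = 6) in ovoid IL6 conceptuses, a log2 fold change of 1.31 ± 0.34 (SE, edgeR adjusted p = 0.99997). ENSBTAG00000019173 (chromosome 29, 37655999 to 37666176) had a log2 fold change of 4.83 ± 1.30 (SE, edgeR adjusted p = 0.99997), with 177 CPM in tubular IL6 replicate 2 and at most 4.82 CPM in the other tubular IL6 conceptuses, and 1.22 as the log2 fold change without that replicate. ENSBTAG00000054971 and ENSBTAG00000049793, on unplaced scaffolds, had log2 fold changes of -1.50 ± 0.40 and -1.36 ± 0.38 (SE, edgeR adjusted p = 0.99997 for both). Of the 514 genes of chromosome X, 139 had a positive and 375 a negative fold change (camera adjusted p = 5.16e-05, and adjusted p = 0.896 with an estimated correlation), and 26 of 27 mitochondrial genes a positive one (camera adjusted p = 0.0446, and adjusted p = 0.896 with an estimated correlation). The mitochondrial share was 2.85% in tubular and 2.50% in ovoid IL6 conceptuses (exact permutation p = 0.467, adjusted p = 0.600). With edgeR, 0 of 14875 genes were called and 417 had an unadjusted p under 0.05, and DESeq2 called 0, with 651. Both counts lie below the 743.75 expected with no difference. Fits of edgeR without 1 conceptus moved the 417 to values from 196 (without ovoid IL6 replicate 1 or tubular IL6 replicate 1) to 869 (without ovoid IL6 replicate 2). Across genes, which are not independent replicates, log2 fold changes of the shape comparison in controls and in IL6 conceptuses had a Pearson r of 0.308 and a Spearman rho of 0.381, and 0 genes were called in either, so no overlap could be counted. Without title code c201, which holds ovoid controls alone, r was -0.0995, and with the title code as a fixed term it was -0.108.

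Male and female conceptuses differed in 8 genes, of which 3 were higher in males and 5 in females, and 6 of the 8 lie on chromosome X. ENSBTAG00000054758 (chromosome X, 77186632 to 77186757) measured 24.3 ± 9.18 CPM (SD, n = 10) in females and 0.761 ± 0.969 CPM (SD, n = 10) in males, a log2 fold change, male over female, of -5.14 ± 0.45 (SE, edgeR adjusted p = 1.06e-05). ENSBTAG00000049740, which lies close by (chromosome X, 77163652 to 77163736), measured 13.3 ± 5.74 CPM (SD, n = 10) in females and 0.496 ± 0.496 CPM (SD, n = 10) in males, a log2 fold change of -4.76 ± 0.46 (SE, edgeR adjusted p = 2.65e-05). For both genes every female value lay above every male value, with 13.1 CPM the lowest female and 2.85 CPM the highest male value for the first, and 6.87 and 1.54 CPM for the second. ENSBTAG00000006472 (chromosome X, 133303369 to 133333184) was higher in males, at 12.3 ± 11.8 CPM (SD, n = 10) against 0.662 ± 0.415 CPM (SD, n = 10) in females, a log2 fold change of 3.80 ± 0.64 (SE, edgeR adjusted p = 0.0254). Its call held in 9 of 20 fits that left out 1 conceptus and was lost without ovoid control replicate 4 or 5, ovoid IL6 replicate 1, 3, 4 or 6, tubular control replicate 1, 2 or 3, or tubular IL6 replicate 2 or 4, with edgeR adjusted p up to 0.158. ENSBTAG00000046366 (chromosome X, 132967787 to 132970684) had 3 to 18 counts in each of the 10 males and 0 in all 10 females, at least 24.1-fold higher in males against a floor of 3 counts over the female group (edgeR adjusted p = 0.0104). That gene lies below the level set for named genes and was chosen after its values were seen. For ENSBTAG00000046366 and ENSBTAG00000006472, counts were assigned by aligned position. Whether the reads of males at these genes came from chromosome X was not tested.

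Genes of chromosome X as a group were lower in males. Of 514 tested, 426 had a negative and 88 a positive fold change, with a median log2 fold change of -0.41 (camera adjusted p = 4.71e-23), and the call held with an estimated correlation (adjusted p = 0.0334). The chromosome X share of counts was 2.82% ± 0.246 (SD, n = 10) in females and 2.11% ± 0.157 (SD, n = 10) in males (permutation p = 3.00e-05 over 100000 permutations, adjusted p = 2.70e-04). The lowest female share, 2.47%, and the highest male share, 2.42%, did not overlap. Chromosome 18 had 532 of 852 genes with a positive fold change in males (camera adjusted p = 0.0254), with an adjusted p = 0.979 with an estimated correlation. DESeq2 called 88 genes between the sexes, among them 7 of the 8, and 40 of the 88 lie on chromosome X, 37 of these higher in females. Without ovoid control replicate 3 edgeR called 23 genes, and with the title code as a fixed term 2. It called 18 without ovoid IL6 replicate 1 and 5 without ovoid IL6 replicate 3 or 6, tubular IL6 replicate 2, or tubular control replicate 1 or 2.

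**Figure D3:**
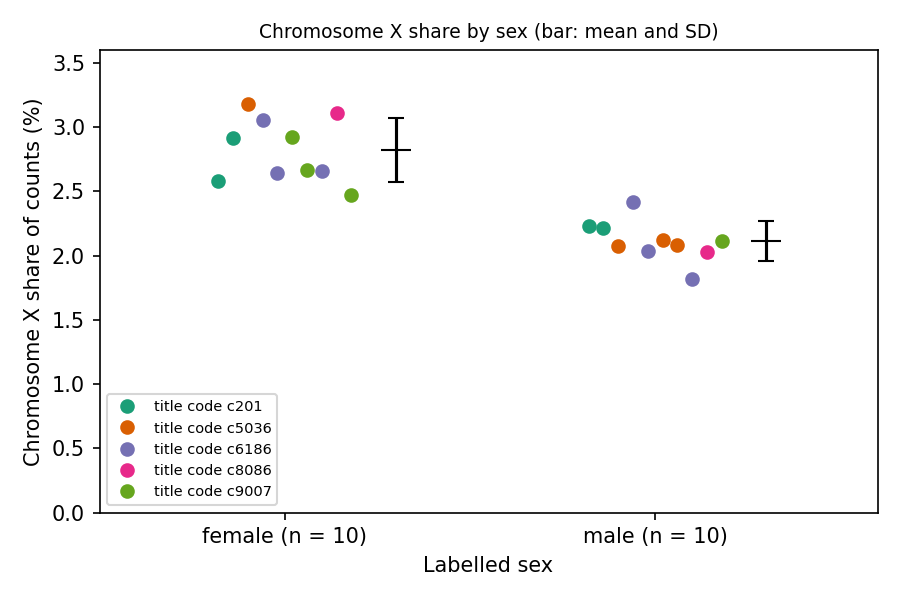
Share of counts in genes of chromosome X (y axis, percent) in the 10 female and 10 male conceptuses (x axis), coloured by title code, with the mean and SD beside the points. Female values lie between 2.47% and 3.18% and male values between 1.82% and 2.42%.

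The difference of the IL6 effect between males and females was tested in ovoid conceptuses, with 2 males and 4 females given IL6. Both of these males are of c6186 and 2 of the 4 females of c9007, so the difference is mixed with title code. ENSBTAG00000016748 (chromosome 2, 120038513 to 120041495) had the smallest p among negative values, with a log2 difference, male minus female, of -6.63 ± 1.27 (SE, edgeR adjusted p = 0.689). It became -11.6 without ovoid IL6 replicate 2, a fit that left 1 male given IL6 and took the spread from other conceptuses. Of the 6 ovoid IL6 libraries 5 had a count of this gene, so the size of that change is uncertain. ENSBTAG00000009778 (chromosome 5, 84749225 to 84789041) had the smallest among positive values, 1.33 ± 0.32 (SE, edgeR adjusted p = 0.689). With edgeR, 0 of 13274 genes were called and 860 had an unadjusted p under 0.05, and DESeq2 called 2, both lower, ENSBTAG00000016748 among them (DESeq2 adjusted p = 3.04e-04). The 860 of edgeR ran, without 1 conceptus at a time, from 395 (without ovoid control replicate 2) to 1788 (without ovoid IL6 replicate 2), and was 130 without c9007 and 187 without c201.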

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

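The values in this part were picked by 1 fixed measure, the distance of a library from the nearest other of its group over the range of the group. For independent groups of normally distributed values, chance exceeds its limit in about 1 in 20. Over 87 groups of values 11 stood out, where 4.35 are expected by chance.

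Ovoid control replicate 3 stood apart from the other 5 ovoid controls in 3 measures. It had 15567 genes with a count, 10.4% of its counts in the 10 most abundant genes against at most 7.39% in the others, and a median Spearman correlation of 0.62 with the other libraries. Its depth of 329666 counts is a possible explanation. When every other library was thinned to that depth, the correlation of replicate 3 was 0.608, while the thinned libraries had medians of 0.825 to 0.916, which argues against low depth alone. At that depth it also had more genes with a count, 15567 against 12408 to 13374. What else sets it apart stays open, and no biological explanation was tested.

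Of the named genes, 8 values stood apart from the rest of their group. ENSBTAG00000007383 was at 6.13 CPM in ovoid IL6 replicate 3, against at most 2.50 CPM in the others of that group, and ENSBTAG00000049793 at 14.03 CPM in ovoid IL6 replicate 1, against at most 8.13 CPM. ENSBTAG00000019173 was at 7.55 CPM in ovoid IL6 replicate 3, against at most 1.32 CPM, and at 177 CPM in tubular IL6 replicate 2, against at most 4.82 CPM. In that same tubular library ENSBTAG00000008714 was at 12.02 CPM, against at most 2.51 CPM. ENSBTAG00000022813 was at 5.30 CPM in tubular IL6 replicate 1, below the 19.7 CPM or more of the others. ENSBTAG00000054829 was at 1.29 CPM in tubular control replicate 4, against at most 0.282 CPM. Among females, ENSBTAG00000021814 (chromosome 9, 12786479 to 12802327), a gene called between the sexes, was at 2.92 CPM in ovoid control replicate 3, against at most 0.288 CPM in the others, but that value is 1 count in the shallowest library.

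Other splits of the conceptuses were counted beside each comparison. For males against females, 1 of 100 splits, the real one, gave as many as 8 genes, and the highest of the others gave 1, so chance can be excluded at that number of splits. For the other comparisons the real count was 0, which every split reaches (100 of 100, and 35 of 35 for IL6 in tubular conceptuses), so these counts of splits say nothing about chance. The highest other count was 0 for IL6 in ovoid conceptuses, 1 in tubular conceptuses, 47 for the average over shapes, 3 for the difference between shapes, 0 for shape in controls and 608 for shape in IL6 conceptuses. Genes at an unadjusted p under 0.05, counted over the same splits after the data were seen, were as many as in the real split in 34 of 100, 7 of 35, 8, 99, 77 and 53 of 100 splits in that order, the real one included, so chance cannot be excluded for these either. On that measure males against females, with 1023 genes, was reached by 25 of 100 splits, so the sexes stand apart from other splits in the 8 genes past the threshold and not in that wider count. The split of IL6 conceptuses with 608 genes put all 4 c9007 conceptuses against the 6 of c6186. Another split, with 552 genes, put 4 c6186 conceptuses on one side, but 4 other splits of that make-up called 0 to 2, so it does not follow the title code. High counts thus also arise where the codes are mixed, and the 608 alone cannot be tied to the title code.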

How the results depend on the processing

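Fits without the shallowest library (ovoid control replicate 3) joined with another choice, and DESeq2 fits without a title code, were chosen after the data were seen. Samples were not paired by replicate number, which only follows their order, and comparisons of shape and sex within title codes were run with the title code as a fixed term. The gene list alternatives were not run, because no member of a list was matched. Counts below are genes past the threshold, and the cause of a change was not tested unless stated.

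For IL6 in ovoid conceptuses the count of 0 became 86 with DESeq2, 154 without c9007, 155 with DESeq2 and 783 without c9007 when the shallowest library was also left out, and 25 and 741 with DESeq2 without c6186 and without c9007. For IL6 in tubular conceptuses it became 1 with DESeq2 and 20 without c9007, both without the shallowest library, and 3 and 302 with DESeq2 without c6186 and without c9007. Averaged over shapes it became 143 with DESeq2, 344 without c9007, 389 (DESeq2), 6 (without c6186) and 2373 (without c9007) when the shallowest library was also left out, and 38 and 2063 with DESeq2 without c6186 and without c9007. For shape in IL6 conceptuses DESeq2 without the shallowest library called 5, and for the sex difference of the IL6 effect DESeq2 called 2. Apart from the fits with 1 conceptus left out, given below, the other settings run gave 0 for these comparisons, as did each setting run for shape in controls and for the difference of the IL6 effect between shapes. In simulated ovoid counts, which hold no title code effect, DESeq2 made 36 false calls and edgeR 3. Fits without c6186 kept fewer IL6 conceptuses than fits without c9007, in ovoid conceptuses and averaged over shapes, and as many in tubular conceptuses.

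For males against females the count of 8 became 88 with DESeq2, 36 with quality weights, 13 with the title code as a random block, 2 with it as a fixed term, 3 without c201 or c8086, and 2 without c5036, c6186 or c9007. Without the shallowest library these were 151 (DESeq2), 61 (weights), 32 (random block), 5 (fixed term), 2 without c5036, 146 without c6186, 4 without c8086 and 11 without c9007.

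The correlation of the shape comparisons across genes, 0.308, became -0.0995 without c201, 0.0330 without c6186, -0.108 with the title code as a fixed term and -0.145 with that and without the shallowest library.

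With 1 conceptus left out at a time, counts ranged from 0 to 11 for IL6 in ovoid conceptuses (11 without ovoid IL6 replicate 5), 0 to 1 averaged over shapes (the same library), and 5 to 23 for sex (23 without ovoid control replicate 3), and stayed at 0 for the other comparisons. The correlation ranged from 0.196 to 0.374. Differences of log2 totals ranged from -0.69 to 0.39 in ovoid and -0.50 to -0.09 in tubular conceptuses, and of the share of the 10 most abundant genes from 0.246 to 1.27 and -0.231 to 2.27 percentage points. Over the named genes 1132 of 1216 values kept their side of the threshold, 48 moved past it and 36 lost it. None that was called in the main or the other fit changed sign. Changes of sign between 2 fits without a call were not counted. Most named genes were printed without passing the threshold, so that they stayed below it was likely from the start. The 36 losses could come only from the genes called between the sexes, so the 1132 does not measure how stable those calls are. Depth limits the genes of low count, since 1 ovoid control held 329666 counts.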

Other observations

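The tests of gene length and of c6186 against c9007, and the comparisons by title code, were chosen after related values had been seen.

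Each title code was compared with all other conceptuses, with terms for shape and sex and without ovoid control replicate 3. The 6 conceptuses of c6186 differed from the other 13 in 4245 of 14738 genes by edgeR, 2220 higher and 2025 lower, of which 1249 changed by a log2 fold change of at least 1. With that replicate kept, the count was 2225. ENSBTAG00000001292 (chromosome 22, 52952571 to 52986619) was higher, with a log2 fold change of 3.90 ± 0.27 (SE, edgeR adjusted p = 1.41e-07), as was ENSBTAG00000020060 (chromosome 3, 21383711 to 21387865) at 2.99 ± 0.23 (SE, edgeR adjusted p = 7.96e-07). ENSBTAG00000000811 (chromosome 7, 4284747 to 4292511) was lower at -1.10 ± 0.10 (SE, edgeR adjusted p = 2.64e-06), as was ENSBTAG00000007739 (chromosome 7, 4599480 to 4602233) at -1.18 ± 0.12 (SE, edgeR adjusted p = 4.85e-06). Of 27 mitochondrial genes, 6 were higher and 0 lower. The same edgeR model called 0 genes for each of c201, c5036, c8086 and c9007, with 790, 916, 279 and 1017 at an unadjusted p under 0.05. In those fits the c6186 conceptuses were among the rest without a term of their own, which can widen the spread. These codes also held 2 to 4 conceptuses, against 6 in c6186. Their counts of 0 are therefore not comparable with 4245 and do not show that c6186 alone stands apart. DESeq2 was not run on these comparisons. Leaving out 1 conceptus of c6186 at a time gave 3151 to 5106 genes. The c6186 libraries also had 7.78% to 14.1% of their counts in the 10 most abundant genes, against 6.40% to 7.55% in the other 13, and median Spearman correlations of 0.876 to 0.951 against 0.950 to 0.970 (0.825 to 0.898 against 0.897 to 0.916 when thinned to the shallowest library).

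The set-apart profile of c6186 was weighed against depth, gene length and IL6. With 19 libraries thinned to 2298491 counts, 3182 genes were called, 2858 of them among the 4245, and with each library corrected for its trend on exonic length 4048 were called, which argues against lower depth or length bias as the whole cause. Of 100 splits of the 19 conceptuses, 1 gave as many genes, the real one, and the highest other gave 5, so chance can be excluded at that number. With a term for each title code over the 19 conceptuses, c6186 differed from c9007, also given IL6, in 1666 of 14738 genes. Thinned libraries gave 1141. Of 100 splits of the 10 IL6 conceptuses, 1 gave as many genes at full depth and 2 when thinned, the real one included. That met the rule for arguing against an IL6 effect of like size in both codes as the whole cause. The rule was written after related values were seen, and the fit on the 10 IL6 conceptuses alone, below, was not stable. The test therefore cannot decide. The highest of the 99 other splits of the 10 IL6 conceptuses gave 1653, and 1540 when thinned, above the real count there, so splits that mix the codes also call many genes. Leaving out 1 IL6 conceptus gave 267 (ovoid IL6 replicate 5) to 2776 genes (ovoid IL6 replicate 1), and 55 to 2089 when thinned. The fit over 19 was chosen after one on the 10 IL6 conceptuses alone, which called 61 genes, 4 when thinned, with 494 and 560 in another split. It called 0 without ovoid IL6 replicate 2, 3, 5 or 6 or tubular IL6 replicate 2 or 4, 33 and 49 without tubular IL6 replicate 3 and 1, and 1130 and 693 without ovoid IL6 replicate 1 and 4, so the difference from c9007 rests on the fit over 19. An IL6 response that arose in 1 code alone, and whatever the code stands for, such as a shared recipient or collection, may each account for it and stay open, since all 6 c6186 conceptuses were given IL6. An IL6 effect of like size in both codes was not excluded either. A difference in RNA or library quality, to which the shares and correlations above may belong, was not tested and stays open too.

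Splits that kept title codes whole were also counted. In ovoid conceptuses the real split, c6186 and c9007 against c201 and c5036, had 0 genes, while c201 and c9007 against c5036 and c6186, which mixes treatments, had 74. Without ovoid control replicate 3 those counts were 0 and 152. In tubular conceptuses the real split and both splits that mix treatments called 0 by edgeR, with or without that library, with 374 in the real split and 1023 (c5036 and c9007 on one side) and 163 (c8086 and c9007) at an unadjusted p under 0.05 with it. Of the 86 genes DESeq2 called for IL6 in ovoid conceptuses, 80 were called again without c9007 and 2 without c6186, ENSBTAG00000022813 and ENSBTAG00000007383. The fit without c9007 kept 4 ovoid IL6 conceptuses and the one without c6186 kept 2. Fewer calls without c6186 can therefore also come from fewer conceptuses. In tubular conceptuses both fits kept equally many IL6 conceptuses. DESeq2 still called far fewer genes there without c6186, as given above, while edgeR called none in either fit. The number of tubular IL6 conceptuses cannot account for that DESeq2 difference, but the fits still differed in conceptuses over both shapes.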
